A study of Caenorhabditis elegans with 9 samples.

How the data were processed

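RNA of 9 samples of wild-type (N2) C. elegans gravid adults was measured on Affymetrix C. elegans Genome Arrays, with 3 samples on each of 3 diets, E. coli OP50, Comamonas DA1877 and Comamonas DA1877 at 1:1000. The design text of the series calls the 3 samples of a condition biological replicates and names OP50 as the reference. Per the labels' protocols, animals grew on NGM plates, RNA was prepared with Trizol and RNeasy columns, and biotin-labelled cRNA was made with an Affymetrix 3' IVT Express kit. Per the submitters' processing notes, the values were made with RMA in the Affymetrix Expression Console, and the deposited values are on the log2 scale, with 1 value per probe set and array and no centring of genes. The versions of both, the chip definition and whether the arrays were normalized together are not given in the sources used here. No detection calls, background values, scan dates or harvest batches were used, since the sources used here do not give them, so values near the lower end of the scale carry little information.

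The deposited values were used without further scaling. Of 22625 probe sets, 77 are Affymetrix controls and were left out, and the other 22548 were tested. Genes were named through the GEO platform annotation, which can be old: 20766 probe sets have 1 gene symbol, 887 have several and 895 are not listed there. Symbols of 20701 probe sets were matched by Entrez number to the reference annotation, which changed 0 symbols. No gene was named from a probe set with several symbols. This gave 17118 genes, of which 2981 have more than 1 probe set, and each gene is represented by its probe set with the highest mean over the 9 arrays. Among the genes named by the rule given below, other probe sets gave another call for pccb-1, mmcm-1, nhr-10, bckd-1A, mlt-7, trxr-1, ifc-2 and ajm-1 in the full diet against OP50, for sams-1, bli-4, ifc-2 and ajm-1 in the 1:1000 diet against OP50, and for mmcm-1, pcca-1, pccb-1, ech-1.1, idh-1, nhr-23, lev-11 and vab-10 in the full against the 1:1000 diet. The IDs of 6711 probe sets end in _s_at, _x_at, _a_at or _r_at and can match several transcripts.

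Differences between diets were tested with limma 3.58.1 in R 4.3.3 (lmFit with a mean per diet, contrasts.fit and eBayes without trend or robust settings), on all 9 arrays, so that the diets share an estimate of the spread with 6 residual degrees of freedom and a prior of 5.84. The test is two-sided, the p-values were adjusted by Benjamini-Hochberg over all probe sets tested within a comparison, and an adjusted p under 0.05 was called. The comparisons were the full diet against OP50, the 1:1000 diet against OP50 and the full against the 1:1000 diet, the last being the test of the difference between the other two. A moderated F-test over both differences from OP50 called 12324 probe sets. A log2 difference is the first diet minus the second, and its SE comes from the fit. The number of arrays limits the precision.

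Gene lists, 31 in number, were fixed before the data were examined, as were the tests, the comparisons, the rule for named genes and all alternatives not described as chosen after seeing the data. Each list was tested with limma's camera, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists within a comparison. The same test with an estimated correlation and limma's fry were run beside it. Families of at least 10 genes sharing the letters of their symbol, 165 in number, were tested in the same way. The propionate shunt and dietary-response regulator lists come from studies of the same dietary contrast and are not independent evidence of direction. Calls "adjusted over the list alone" used Benjamini-Hochberg over the members of the list.

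Named genes were chosen by a rule. It took, in each comparison, the 10 genes with the largest positive and the 10 with the largest negative log2 difference among those called and without overlap between the arrays of both diets, up to 4 members with the smallest adjusted p of each list, all measured members of both propionate lists, and metr-1, mtrr-1, sams-1, nhr-10 and nhr-68. A gene named in any comparison may be given in the others. Members outside the rule were named only after their values were seen, mainly where a count was 5 or fewer.

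The alternatives were arrays median-centred, quantile normalization, the lowest 30% of probe sets left out, only plain _at probe sets, a trended and robust variance prior, array weights, the replicate number as a block, an adjusted p under 0.01, a minimum of 2-fold, only the 6 arrays compared, each array left out in turn, and the mean of a gene's probe sets. Chosen after seeing the data were a scaling that sets the mean of the hybridisation controls (18 probe sets) equal, the removal of 3745 germline-like probe sets, meaning the sperm, oocyte and germline list genes and probe sets correlated above 0.9 with the mean of the sperm or oocyte list over the same 9 arrays, so that the diet differences themselves decide what is removed, and the alternatives for the gene families. The covariance of the differences on both Comamonas diets was compared with 20 simulations of 9 arrays without any change. Noise was drawn independently for each probe set and array, around the probe set's mean and with its residual SD. Both comparisons of a simulation shared its simulated OP50 arrays. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

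The tests were tested on simulated data with known changes among 22548 probe sets. Of 50 genes per size and comparison, a log2 change of 0.5 was called for 56%, 42% and 48% in the 3 comparisons, a change of 1 for 100%, 86% and 94%, and a change of 2 for 100%, 98% and 100%. At most 0.0895% of unchanged probe sets were called. Camera called the list that was shifted and 0 of the 30 other lists. The simulated genes varied independently of each other, so this could not show false list calls that arise from correlated genes.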

Results

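Transcript levels were measured in 9 samples of wild-type (N2) Caenorhabditis elegans collected as gravid adults, 3 biological replicates on each of 3 bacterial diets. The diets were E. coli OP50, the standard laboratory food and the reference here, Comamonas DA1877, called the full Comamonas diet, and Comamonas DA1877 at 1:1000, called the 1:1000 diet. The labels do not say in what the 1:1000 diet was diluted. Each sample was hybridised to 1 Affymetrix C. elegans Genome Array, which gave a log2 value for 22548 probe sets besides the controls. The number of arrays limits the precision, and the typical SE of a difference between diets was 0.10 on the log2 scale.

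Arrays of the same diet resembled each other closely. Across probe sets, which are not independent replicates, Pearson's r was 0.995 to 0.998 in the 9 pairs of arrays of the same diet and 0.947 to 0.973 in the 27 pairs of different diets. The first principal component held 55% of the variance and the second held 37.6%. The mean array median was 5.25 ± 0.01 on OP50, 5.35 ± 0.03 on the 1:1000 diet and 5.43 ± 0.01 on the full diet (SD, n = 3). The bacterial hybridisation controls, which are added in equal amount to each sample before hybridisation, averaged 9.86 ± 0.17 on OP50, 10.14 ± 0.04 on the 1:1000 diet and 9.84 ± 0.12 on the full diet (SD, n = 3). The sign of a difference of that size that involves the 1:1000 diet can change with the scaling, and counts adjusted over the list alone are printed beside those over all probe sets where they differ or are said to be the same.

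The first comparison set the full Comamonas diet against OP50 and asks which transcripts the bacterial diet changes. The enzymes of the propionate shunt, a route of propionate breakdown that does not need vitamin B12, all fell. The transcript of acdh-1, the acyl-CoA dehydrogenase that opens the shunt, fell by 8.21 on the log2 scale (SE 0.15, n = 3 per diet), which is a 297-fold lower level (adjusted p = 3.37e-12). Its mean log2 value was 12.98 ± 0.22 on OP50 and 4.77 ± 0.20 on the full diet (SD, n = 3), the latter below the array median. Signal over background is not known there, so the size of this fall is uncertain. The next enzymes of the route also fell: hphd-1, an oxidoreductase, by 14.7-fold, ech-6 by 3.85-fold and hach-1 by 3.64-fold, while alh-8 changed least, with a log2 difference of -0.52. All 5 of 5 listed genes passed the test, also when adjusted over the list alone, and their median log2 difference was -1.95. The list as a whole was lower than other genes by camera (adjusted p = 1.23e-05; adjusted p = 0.27 with an estimated correlation). This list came from studies of the same dietary contrast and is not independent evidence of its direction.

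The B12-dependent route of propionyl-CoA breakdown did not move one way. Both subunits of propionyl-CoA carboxylase rose, pcca-1 by 0.45 and pccb-1 by 0.48 on the log2 scale, though another probe set of pccb-1 gave another call. The adenosylcobalamin-related genes mmaa-1 (-0.77) and mmab-1 (-0.39) and the mutase gene mmcm-1 (-0.34, with another probe set giving another call) fell, while mce-1 differed by -0.11 (adjusted p = 0.307). In all, 2 of 6 listed genes rose and 3 fell, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.652). With arrays median-centred, 1 rose and 4 fell. Of the 14 methionine and folate cycle genes measured, 3 rose and 10 fell, also when adjusted over the list alone (list adjusted p = 0.159). The S-adenosylmethionine synthetase genes sams-5 and sams-1 rose by 2.02 and 1.01, and pmt-1, a methyltransferase of phosphatidylcholine synthesis, rose by 1.1. The methionine synthase gene metr-1 and its reductase mtrr-1 fell by 0.48 and 0.89. In transsulfuration, the cystathionine beta-synthase gene cbs-1 rose by 2.87 and cth-2 by 0.80, cth-1 fell by 1.2 and cbs-2 differed by -0.07, and the list of 4 did not pass (adjusted p = 0.312). The nuclear receptor gene nhr-68 fell by 0.72, and nhr-10, another nuclear receptor gene that acts on acdh-1, differed by 0.31 (adjusted p = 0.107), with another of its probe sets giving another call.

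**Figure D1:**
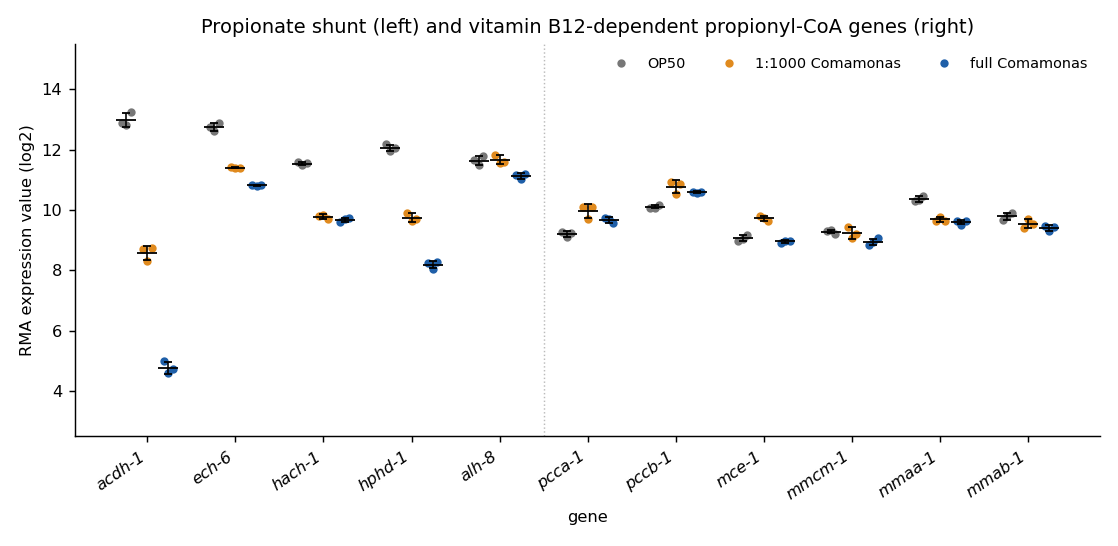
Log2 values (y axis) of the propionate shunt genes and of the B12-dependent propionyl-CoA genes (x axis) on OP50, the 1:1000 diet and the full Comamonas diet; points are arrays (n = 3 per diet), lines are means and bars are SD. The level of acdh-1 steps down from 12.98 on OP50 to 8.59 on the 1:1000 diet and 4.77 on the full diet.

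Sperm transcripts held many of the largest increases on the full diet. The 10 largest were those of msd-4, nspd-4, msp-50, msp-3, C04F12.7, msp-64, F27C1.1, msp-45, nspd-2 and msp-152, with log2 differences from 6.29 for msd-4 (78.2-fold, SE 0.16, adjusted p = 1.45e-11) down to 6.01 for msp-152. The msp and msd genes encode the major sperm protein and its relatives, and many of their probe sets match several near-identical genes, so a value cannot be assigned to a single member. Of the 36 sperm-list genes measured, 30 rose and 2 fell, also when adjusted over the list alone, with a median log2 difference of 5.37 (camera adjusted p = 1.01e-23; adjusted p = 0.15 with an estimated correlation). The 2 that fell, named after their values were seen, were spe-44, a regulator of spermatogenesis genes, and spe-39, a vesicle trafficking gene, each by 0.93. Over the 10 members of the list with plain _at probe sets, which were designed against a single transcript, 7 rose and the median was 0.66. The list's median thus rests largely on its other probe sets, which can match several transcripts. Kind of gene and kind of probe set were not separated here. Among the plain probe sets, that of spe-11, a sperm-supplied factor, rose by 4.37, from 4.01 ± 0.11 to 8.38 ± 0.11 (SD, n = 3; adjusted p = 5.63e-12).

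Oocyte and germline transcripts fell on the full diet. All 22 of 22 genes of the oocyte, eggshell and maternal list fell, also when adjusted over the list alone, with a median of -0.87 (camera adjusted p = 8.55e-08; adjusted p = 0.36 with an estimated correlation). Among them were the eggshell gene cpg-2 (-0.86), the germline fate gene pie-1 (-0.86) and the translational regulator puf-11 (-0.97). Of 30 germline and meiosis genes, 0 rose and 17 fell, 18 when adjusted over the list alone, including the cyclin E gene cye-1 (-1.13) and the replication helicase gene mcm-3 (-1.04), and the list median was -0.42 (camera adjusted p = 1.97e-04; adjusted p = 0.36 with an estimated correlation). With arrays median-centred 28 fell and the median was -0.60. Of 22 embryonic zygotic genes, 12 fell, 13 when adjusted over the list alone, and 2, elt-3 by 1.68 and nob-1 by 0.39, rose, nob-1 being named after its values were seen, and the list did not pass (adjusted p = 0.0622). The yolk protein genes vit-1 (-0.46), vit-4 (-0.35), vit-5 (-0.31) and vit-6 (-0.32) fell and vit-2 differed by -0.25. That is 4 of 5 vitellogenins, or 5 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0755). With the hybridisation controls set equal, an alternative chosen after seeing the data, 1 fell. The vitellogenin median was -0.30 there and -0.32 with the deposited scaling, so the difference itself hardly moved.

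Many defence, detoxification, cuticle, muscle and neuron genes rose on the full diet. Of 58 innate immune effector genes, 25 rose and 10 fell, 11 when adjusted over the list alone, led by dod-22 (3.83), dod-17 (3.10), sysm-1 (2.40) and the lectin gene clec-86 (3.04). Their median was 0.13, which turned to -0.05 with arrays median-centred, where 24 rose and 20 fell (camera adjusted p = 3.11e-04; adjusted p = 0.51 with an estimated correlation). Of 61 xenobiotic detoxification genes, 33 rose and 8 fell, or 35 and 9 when adjusted over the list alone, with glutathione transferase genes gst-6 (2.88), gst-38 (3.03) and gst-5 (2.46) among them and a median of 0.39 (camera adjusted p = 6.39e-06; adjusted p = 0.36 with an estimated correlation). With arrays median-centred, 25 of them rose, 17 fell and the median was 0.21. Of 9 adult cuticle collagen genes, 6 rose and 0 fell, also when adjusted over the list alone, led by col-139 (4.51) and col-129 (3.95), with a median of 0.65 (camera adjusted p = 7.02e-05; adjusted p = 0.27 with an estimated correlation). Of 25 body-wall muscle markers, 18 rose, among them the troponin I gene tni-1 (1.86) and the myosin gene unc-54 (1.44), and 1, tnt-3 (-1.28), named after its values were seen, fell, also when adjusted over the list alone. The muscle median was 0.76 (camera adjusted p = 1.74e-06; adjusted p = 0.36 with an estimated correlation). Of 40 neuron markers, 19 rose, including the synaptic gene ric-4 (2.42) and the touch-neuron gene mec-17 (2.88), and 2, unc-119 (-0.75) and tba-1 (-0.53), named after their values were seen, fell, also when adjusted over the list alone. The neuron median was 0.21 (camera adjusted p = 5.42e-05; adjusted p = 0.27 with an estimated correlation), or 0.03 with arrays median-centred, where 17 rose and 9 fell.

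Of 20 genes of fatty acid synthesis, desaturation and elongation, 10 rose and 2 fell, also when adjusted over the list alone, with the desaturase gene fat-3 higher by 0.91 and fat-5 lower, at -3.25. The other gene that fell, elo-3 (-0.31), was named after its values were seen, and the list passed (adjusted p = 0.0417; adjusted p = 0.53 with an estimated correlation). It did not pass in 7 of 15 alternatives, the omission of single arrays among them (adjusted p up to 0.329). With arrays median-centred, 7 rose and 4 fell. Of 25 fatty acid oxidation genes, 13 rose and 6 fell, also when adjusted over the list alone, from acdh-8 (4.25) and ech-9 (2.49) to acs-2 (-3.09) and acdh-2 (-3.38), and the list did not pass (adjusted p = 0.0884). With arrays median-centred, 9 rose and 9 fell. Of 75 cytosolic ribosomal protein genes, 2 rose, rpl-23A.1 (0.58) and rpl-11.2 (0.45), and 17 fell, 6 when adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.00879; adjusted p = 0.53 with an estimated correlation). The number that fell depends on the scaling: 70 with arrays median-centred, 25 after quantile normalization and 0 with the hybridisation controls set equal. With those controls equal the list did not pass (camera adjusted p = 0.223), though its median, -0.14, hardly moved. The calls were thus lost there without much change in the difference itself. Of 17 intestine markers, 7 rose and 3 fell, also when adjusted over the list alone. The intermediate filament genes ifc-2 (1.72, with another probe set giving another call) and ifb-2 (1.3) rose, while ges-1 (-0.52), mtl-2 (-0.61) and end-1 (-0.48), named after their values were seen, fell. The intestine median was 0.18, and about 0 and of the other sign with arrays median-centred (camera adjusted p = 0.0433; adjusted p = 0.53 with an estimated correlation). In 5 of 15 alternatives, the omission of single arrays among them, this list did not pass (adjusted p up to 0.125). Of 16 heat-shock genes, 10 fell, among them hsp-16.2 (-1.75), hsp-16.41 (-1.76) and hsp-70 (-0.95), and 4, hsp-25 (0.99), hsp-17 (0.49), hsp-43 (0.47) and hsp-12.6 (0.42), rose, the last 3 named after their values were seen, also when adjusted over the list alone (adjusted p = 0.0772).

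The remaining lists did not pass against OP50 on the full diet. By the test over all probe sets, 11 of 26 TCA cycle, glyoxylate and gluconeogenesis genes rose and 3 fell (13 and 6 adjusted over the list alone), as did 4 and 1 of 10 branched-chain amino acid genes, 14 and 10 of 38 other cuticle collagen and moulting genes (15 and 10 adjusted over the list alone) and 8 and 3 of 41 oxidative phosphorylation genes. Of 20 intracellular pathogen response genes, 3 rose and 2 fell (3 and 1 adjusted over the list alone), of 21 oxidative stress and metal genes 4 rose and 7 fell, and of 24 unfolded protein response genes 3 rose and 9 fell (4 and 9 adjusted over the list alone). The dietary-response regulators, a list that is not independent evidence because it came from studies of this diet, split into 11 of 32 higher and 11 lower (12 and 11 adjusted over the list alone). Of 31 DAF-16 target and insulin genes 9 rose and 4 fell (10 and 4 adjusted over the list alone), of 27 intestinal protease and lysosome genes 11 and 7 (12 and 7 adjusted over the list alone), of 21 pharynx markers 6 and 2, and of 19 hypodermis, gland or vulva markers 8 and 4 (9 and 5 adjusted over the list alone). Among the single genes, msrp-2 rose by 4.81, the insulin-like gene ins-7 by 2.68 and the pharynx troponin C gene tnc-2 by 1.87. The nuclear receptor gene nhr-114 fell by 1.97 and the gluconeogenesis gene pck-1 by 0.74. Median, mean and test differed in sign for the other collagens (median 0.14, mean -0.04), the intracellular pathogen list (-0.02, 0.05), oxidative stress (-0.09, 0.14), the dietary regulators (median -0.10, tested direction up) and pharynx (-0.03, 0.12). Where a count was 5 or fewer, its members, named after their values were seen, were sucl-2, mdh-1 and pck-1 (TCA, lower), bcat-1, bckd-1A, dld-1 and acdh-4 (branched-chain, higher) and acdh-3 (lower), nduf-2.2, ucr-2.3 and cox-11 (oxidative phosphorylation, lower), skr-3, skr-5 and cul-6 (intracellular pathogen, higher) and pals-28 and skr-4 (lower). They were also msrp-2, ftn-1, ftn-2 and cdr-1 (oxidative stress, higher), hsp-3, pdi-2 and dve-1 (unfolded protein response, higher), sod-3, mtl-2, age-1 and akt-1 (DAF-16, lower), pha-4 and phat-6 (pharynx, lower) and nhr-25, wrt-2, wrt-10 and cdh-3 (hypodermis, lower). With arrays median-centred the higher and lower counts were 5 and 8 in the TCA list, whose median was then about 0, 4 and 3 in the branched-chain, 12 and 16 in the other collagen, 4 and 19 in the oxidative phosphorylation, 3 and 7 in the intracellular pathogen and 6 and 15 in the dietary regulator list. They were 6 and 9 in the DAF-16, 10 and 12 in the protease, 4 and 9 in the pharynx and 7 and 6 in the hypodermis list. In the oxidative stress list they were 4 and 12, or 4 and 4 with the hybridisation controls set equal instead. The oxidative stress median was -0.07 in the latter case, close to that with the deposited scaling. The medians of the branched-chain (-0.14), other collagen (-0.04), oxidative phosphorylation (-0.13), DAF-16 (-0.16) and protease (-0.05) lists turned negative.

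Besides acdh-1 and hphd-1, the 10 largest decreases on the full diet were the lectin genes clec-266 (-4.04) and clec-47 (-3.88), C09B8.4 (-3.81), the chemoreceptor gene srh-237 (-3.70), the folate transporter gene folt-2 (-3.40), F15E6.4 (-3.39), acdh-2 (-3.38) and fat-5 (-3.25). In all, 3972 of 22548 probe sets were higher and 5810 lower on the full diet by limma with Benjamini-Hochberg adjustment, together 43.4%. A change of at least 2-fold was called for 1474 higher and 552 lower probe sets, which represent 1226 and 405 genes. The split of small changes depends on the scaling: with arrays median-centred, which shifts the median difference of all probe sets to -0.25, 3091 were higher and 12419 lower.

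The second comparison set the 1:1000 diet against OP50 and asks which transcripts that diet changes. The transcript of acdh-1 fell by 4.40 on the log2 scale (SE 0.15, n = 3 per diet), 21.1-fold, to a mean of 8.59 ± 0.23 (SD, n = 3; adjusted p = 1.83e-09). The shunt genes hphd-1 (-2.32), hach-1 (-1.76) and ech-6 (-1.36) fell as well, and alh-8 differed by 0.02 (adjusted p = 0.897), so that 4 of 5 listed genes fell, also when adjusted over the list alone. The list median was -1.76 (camera adjusted p = 2.57e-04; adjusted p = 0.32 with an estimated correlation), and as before the list is not independent evidence. In the B12-dependent route pcca-1 (0.75), pccb-1 (0.67) and mce-1 (0.66) rose, mmaa-1 fell by 0.68, and mmcm-1 (-0.05, adjusted p = 0.782) and mmab-1 (-0.24, adjusted p = 0.0733) did not pass. That is 3 of 6 higher and 1 lower, or 3 and 2 when adjusted over the list alone (list adjusted p = 0.55).

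Of 14 methionine and folate cycle genes, 8 fell on the 1:1000 diet, among them metr-1 (-1.06), mtrr-1 (-1.07), sams-4 (-1.29) and mthf-1 (-1.25), and 3, pmt-1 (0.52), atic-1 (1.07) and dao-3 (0.36), named after their values were seen, rose, also when adjusted over the list alone. The list median was -0.62 (camera adjusted p = 0.0139; adjusted p = 0.34 with an estimated correlation), and sams-1 differed by -0.17 (adjusted p = 0.249), with 2 other probe sets giving another call. With the hybridisation controls set equal, 1 gene of the list rose and 10 fell, and the median was -0.91. In transsulfuration cbs-1 (1.56), cth-2 (1.04) and cth-1 (0.75) rose and cbs-2 differed by -0.14, so that 3 of 4 rose and 0 fell, also when adjusted over the list alone. The transsulfuration median was 0.90 (camera adjusted p = 0.0466; adjusted p = 0.34 with an estimated correlation). This list of 4 did not pass in 5 of 15 alternatives, the omission of single arrays among them (adjusted p up to 0.0624). Of the regulators, nhr-10 rose by 0.59, nhr-68 differed by 0.29 (adjusted p = 0.143) and nhr-114 fell by 2.2.

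Many oocyte and germline transcripts fell further on the 1:1000 diet than on the full diet. Of 22 oocyte, eggshell and maternal genes, 20 fell and 1 rose, also when adjusted over the list alone, with a median of -2.15 (camera adjusted p = 1.83e-13; adjusted p = 0.32 with an estimated correlation). The RNA-binding protein genes puf-5 (-2.86) and oma-2 (-2.47), cpg-2 (-2.50) and pie-1 (-2.21) fell, perm-2, named after its values were seen, rose by 0.38, and perm-4 differed by 0.16. Of 30 germline and meiosis genes, 26 fell and 0 rose, also when adjusted over the list alone, including cyb-1 (-1.69), a mitotic cyclin gene, and mcm-3 (-2.2), and the median was -0.93 (camera adjusted p = 4.89e-11; adjusted p = 0.32 with an estimated correlation). Of 36 sperm genes, 24 rose and 3 fell, also when adjusted over the list alone, with msp-152 (2.63), msp-59 (2.63) and msp-55 (2.67) among them. The sperm median was 1.77 (camera adjusted p = 5.65e-08; adjusted p = 0.32 with an estimated correlation). The 3 that fell, named after their values were seen, were spe-6 (-0.69), spe-39 (-1.41) and spe-44 (-1.32), and over the 10 members with plain _at probe sets the median was 0.09. The plain probe set of spe-11 differed by 0.11 (adjusted p = 0.399). Of 22 embryonic zygotic genes 4 rose and 6 fell, also when adjusted over the list alone, with die-1 at -2.31 and elt-7 at 0.92 (list adjusted p = 0.494). Only 2 rose and 11 fell with the hybridisation controls set equal, where the median went from -0.05 to -0.33. The other 3 that rose, elt-3 (0.60), cwn-1 (0.77) and nob-1 (0.46), were named after their values were seen.

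Many defence and detoxification genes rose on the 1:1000 diet. Of 58 innate immune effector genes, 34 rose, 35 when adjusted over the list alone, and 5 fell, with a median of 1.06 (camera adjusted p = 7.53e-09; adjusted p = 0.32 with an estimated correlation). The immune median was 0.77 with the hybridisation controls set equal, with 32 higher and 9 lower. The gene sysm-1 rose by 4.30, irg-5 by 3.96, clec-67 by 3.84 and dod-22 by 3.53, while clec-47 (-5.04) and the lysozyme genes lys-4 (-1.79), lys-5 (-1.62), lys-6 (-1.88) and lys-7 (-0.39) fell, the lysozyme genes being named after their values were seen. Of 61 detoxification genes, 35 rose, led by gst-38 (4.01), gst-20 (3.27) and gst-5 (2.76), and 2, gst-7 (-0.53) and ugt-63 (-0.55), named after their values were seen, fell, also when adjusted over the list alone. The detoxification median was 0.68 (camera adjusted p = 2.28e-07; adjusted p = 0.32 with an estimated correlation). It was 0.40 with the hybridisation controls set equal, with 32 higher and 11 lower. Of 16 heat-shock genes 7 rose and 7 fell, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.482), its median of 0.01 being negative under each other scaling. The inducible small heat-shock genes hsp-16.41 (3.28) and hsp-16.2 (2.88), hsp-70 (2.44) and hsp-17 (2.17) rose, and sip-1, a small heat-shock gene of the embryo, fell by 1.99. Besides these, pud-4 and pud-3 rose by 6.0 and 5.21, nspg-7.2 by 4.77, C32H11.4 by 4.24, txt-4 by 4.08, the sphingomyelinase gene asm-3 by 4.03 and C15A11.4 by 3.90, which with sysm-1, gst-38 and irg-5 are the 10 largest increases. The 10 largest decreases were clec-47, acdh-1, puf-5, nspe-1 (-4.47), meg-1 (-3.53), C09B8.4 (-3.24), T06D4.1 (-2.96), acdh-2 (-2.93), ZK829.9 (-2.88) and F02H6.4 (-2.88).

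Muscle and intestine markers mostly rose on the 1:1000 diet. Of 25 body-wall muscle markers 20 rose, 21 when adjusted over the list alone, among them atn-1 (1.56), csq-1 (1.46) and tni-1 (1.42), and tnt-3 fell by 0.49, named after its values were seen. The muscle median was 1.04 (camera adjusted p = 2.77e-08; adjusted p = 0.33 with an estimated correlation). Of 17 intestine markers 12 rose, 15 when adjusted over the list alone, with the proton pump gene vha-6 (1.31) and the phosphatase gene pho-1 (1.11), and cpr-1 fell by 1.28, named after its values were seen. The intestine median was 0.73 (camera adjusted p = 1.46e-04; adjusted p = 0.34 with an estimated correlation), or 0.45 with the hybridisation controls set equal. Of 27 intestinal protease and lysosome genes 20 rose and 5 fell, also when adjusted over the list alone, with the acid ceramidase gene asah-1 at 3.19 and asp-14 at 2.40. The protease median was 0.44 (camera adjusted p = 6.56e-04; adjusted p = 0.40 with an estimated correlation), or 0.16 with the hybridisation controls set equal, an alternative chosen after seeing the data, with 11 higher and 6 lower. The 5 that fell, named after their values were seen, were cpr-1 (-1.28), cpr-4 (-1.04), cpr-5 (-1.07), asp-13 (-0.28) and cup-5 (-1.29). Of 40 neuron markers 17 rose, with unc-64 (1.5) and sbt-1 (1.19), and 2, unc-119 (-0.35) and tba-1 (-0.97), named after their values were seen, fell, also when adjusted over the list alone. The neuron median was 0.19, which turned to -0.09 with the hybridisation controls set equal, where 8 rose and 2 fell (camera adjusted p = 0.00348; adjusted p = 0.33 with an estimated correlation). Of 19 hypodermis, gland or vulva markers 10 rose and 2 fell, 11 and 3 when adjusted over the list alone, with wrt-10 at 1.70 and dpy-7 at 0.95. The hypodermis median was 0.31 (camera adjusted p = 0.0377; adjusted p = 0.32 with an estimated correlation), and the 2 that fell, nhr-25 (-0.34) and cdh-3 (-0.74), were named after their values were seen. It was 0.02 with the hybridisation controls set equal, with 3 higher and 3 lower, and the list did not pass in 3 of 15 alternatives (adjusted p up to 0.0621). Of 9 adult cuticle collagen genes 4 rose and 0 fell, or 6 and 0 when adjusted over the list alone, with col-129 (1.49), col-139 (1.38), col-19 (0.55) and col-38 (0.49) higher. The adult collagen median was 0.30 (camera adjusted p = 0.0243; adjusted p = 0.34 with an estimated correlation), or 0.02 with the hybridisation controls set equal, with 2 higher and 0 lower.

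Among metabolic lists, 17 of 25 fatty acid oxidation genes rose and 6 fell, also when adjusted over the list alone. The peroxisomal oxidase gene acox-1.1 (1.15) and the lipase gene lipl-5 (1.32) rose, and acdh-2 (-2.93) and acs-2 (-2.37) fell. The fatty acid oxidation median was 0.68 (camera adjusted p = 0.0243; adjusted p = 0.43 with an estimated correlation), or 0.40 with the hybridisation controls set equal, with 13 higher and 6 lower. Of 20 genes of fatty acid synthesis, desaturation and elongation 13 rose and 3 fell, also when adjusted over the list alone, with fat-6 (1.02) and the lipid regulator sbp-1 (0.87) higher and fat-5 lower, at -2.23. The fatty acid synthesis median was 0.50 (camera adjusted p = 0.0277; adjusted p = 0.43 with an estimated correlation). It was 0.21 with the hybridisation controls set equal, where 6 rose and 4 fell and the list did not pass (adjusted p = 0.105). The other 2 that fell, fasn-1 (-0.73) and fat-7 (-0.88), were named after their values were seen. Of 75 ribosomal protein genes 3 rose and 5 fell, or 2 and 1 when adjusted over the list alone, with rpl-23A.1 at 0.91, rpl-11.2 and rpl-41.1 higher and rpl-10L, rpl-10a, rpl-11.1, rpl-23A.2 and rpl-7 lower, partly named after their values were seen. The ribosomal median was -0.09 (camera adjusted p = 0.0243; adjusted p = 0.46 with an estimated correlation). This list did not pass in 4 of 15 alternatives, the omission of single arrays among them. With arrays median-centred 2 rose and 32 fell, and with the hybridisation controls set equal 1 rose and 61 fell (median -0.38) but the list did not pass (adjusted p = 0.168). Of 5 vitellogenins 4 rose and 0 fell, or 5 and 0 when adjusted over the list alone, with vit-2 (0.52), vit-1 (0.42), vit-6 (0.25) and vit-4 (0.22) higher and vit-5 differing by 0.17. Their median of 0.25 turned to -0.03 with the hybridisation controls set equal, vit-4 and vit-6 turned negative too, and the list did not pass (adjusted p = 0.0821).

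The other lists did not pass against OP50 on the 1:1000 diet. In the TCA cycle, glyoxylate and gluconeogenesis list 11 of 26 rose and 5 fell (12 and 5 adjusted over the list alone), with idhg-2 (1.41) and pck-1 (1.31) higher. Of 10 branched-chain amino acid genes 5 rose and 1 fell (6 and 2 adjusted over the list alone), of 38 other collagen and moulting genes 13 and 5, and of 41 oxidative phosphorylation genes 14 and 5 (15 and 5 adjusted over the list alone). Of 21 oxidative stress and metal genes 11 rose and 2 fell (11 and 3 adjusted over the list alone), with cdr-1 at 1.72, and of 20 intracellular pathogen genes 4 rose and 0 fell, with the ubiquitin ligase genes skr-3 (1.59) and cul-6 (1.02) higher. Of 24 unfolded protein response genes 10 rose and 10 fell, and of 21 pharynx markers 1 rose and 1 fell, namely tnt-4 (0.33) and tni-4 (-0.22), with 0 and 0 adjusted over the list alone. Of 32 dietary-response regulators, again not independent evidence, 15 rose and 11 fell (15 and 12 adjusted over the list alone), with pqm-1 (1.73) and nhr-8 (1.33) higher. Of 31 DAF-16 target and insulin genes 13 rose and 3 fell, with dod-3 at 3.21 and ins-7 at 2.1 and the kinase gene age-1 at -1.83. Where a count was 5 or fewer, its members, named after their values were seen, were idh-1, idhg-1, sucg-1, sucl-2 and pyc-1 (TCA, lower), bcat-1, bckd-1A, bckd-1B, dld-1 and acdh-9 (branched-chain, higher), acdh-3 (lower), noah-2, fbn-1, bli-4, nhr-23 and nhr-25 (other collagens and moulting, lower) and nduf-2.2, ucr-2.3, cox-11, cox-15 and asb-1 (oxidative phosphorylation, lower). They were also prdx-3 and trxr-1 (oxidative stress, lower), skr-3, skr-4, cul-6 and fbxa-182 (intracellular pathogen, higher) and daf-16, age-1 and akt-1 (DAF-16, lower). Median, mean and test differed in sign for the unfolded protein response list (median 0.01, mean -0.04). With the hybridisation controls set equal, higher and lower counts were 6 and 7 in the TCA, 2 and 4 in the branched-chain, 7 and 9 in the other collagen, 4 and 7 in the oxidative phosphorylation, 7 and 6 in the oxidative stress and 3 and 3 in the intracellular pathogen list. They were 2 and 12 in the unfolded protein response, 0 and 6 in the pharynx, 9 and 13 in the dietary regulator and 7 and 6 in the DAF-16 list. The medians of the TCA (-0.09), branched-chain (-0.02), other collagen (-0.09), oxidative phosphorylation (-0.16), oxidative stress (-0.02), intracellular pathogen (-0.22), unfolded protein response (-0.27), pharynx (-0.23), dietary regulator (-0.10) and DAF-16 (-0.13) lists turned negative.

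In all, 4787 probe sets were higher and 5087 lower on the 1:1000 diet by limma with Benjamini-Hochberg adjustment, 43.8% of those tested, and 1441 were higher and 1710 lower by at least 2-fold. The split moved with the scaling: it was 3770 higher and 6083 lower with arrays median-centred, and 2613 higher and 8221 lower with the hybridisation controls set equal, which shifts the median difference of all probe sets to -0.26.

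**Figure D2:**
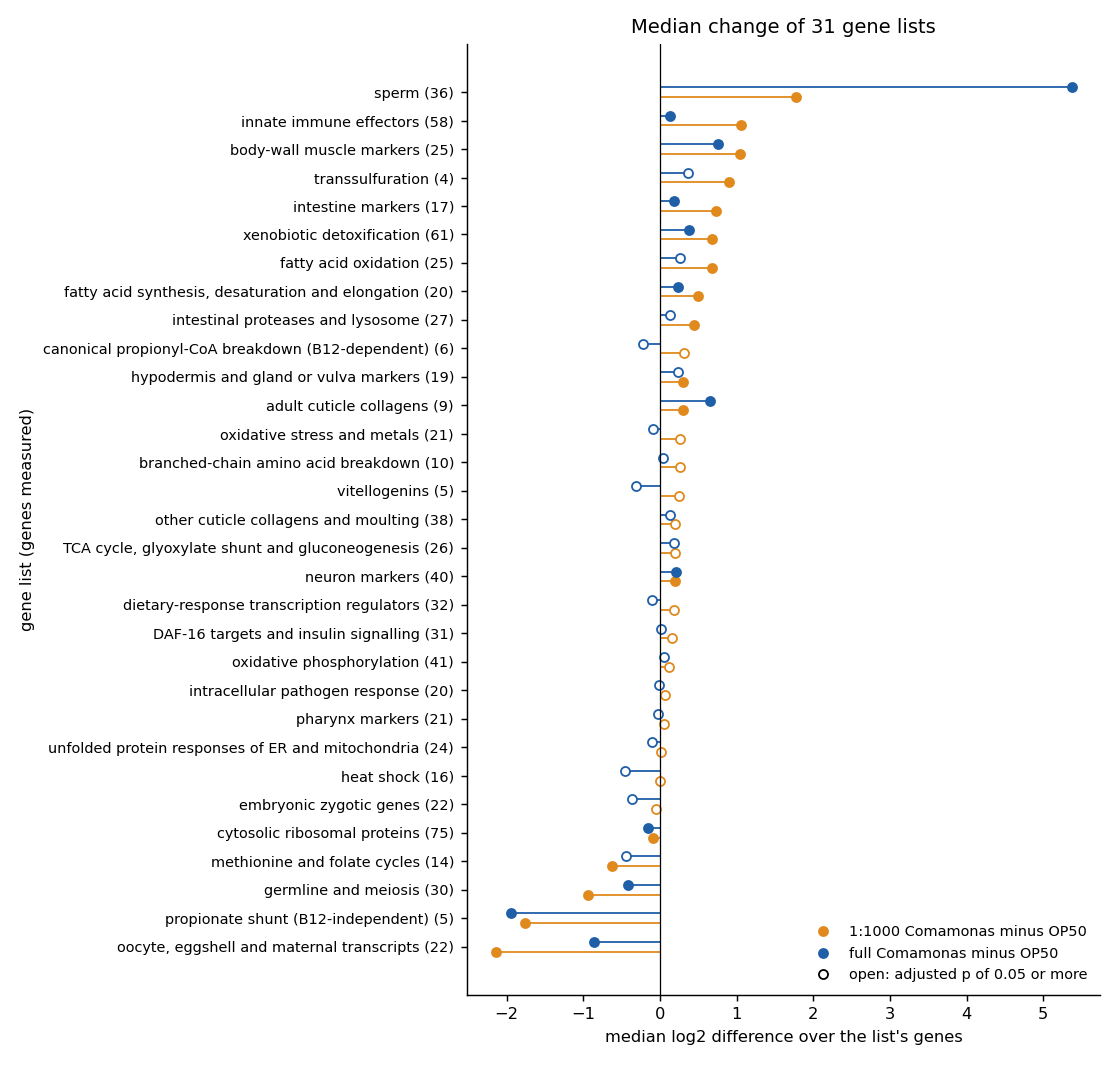
Median log2 difference from OP50 (x axis) of the 31 gene lists (y axis) on the full and the 1:1000 Comamonas diet; each point is a list, filled where camera passed and open where it did not. The sperm median is 5.37 on the full and 1.77 on the 1:1000 diet, and the oocyte median is -0.87 and -2.15; medians near 0 change sign with the scaling, such as the innate immune list on the full diet (0.13, or -0.05 with arrays median-centred).

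The third comparison set the full against the 1:1000 diet. What else the 1:1000 food held is not known, so this does not test the amount of Comamonas alone. The transcript of acdh-1 was lower on the full diet by a further 14.1-fold (log2 difference -3.81, SE 0.15, n = 3 per diet, adjusted p = 8.29e-10), a size that is uncertain for the same reason as against OP50. The genes hphd-1 (-1.56), ech-6 (-0.59) and alh-8 (-0.54) were lower too. In contrast hach-1 differed by -0.11 (adjusted p = 0.339). That is 4 of 5 shunt genes lower and 0 higher, also when adjusted over the list alone. With the hybridisation controls set equal, 2 were lower and the median was -0.28. The shunt median with the deposited scaling was -0.59 (camera adjusted p = 0.00267; adjusted p = 0.43 with an estimated correlation), again not independent evidence. In the B12-dependent list mce-1 (-0.77) and mmcm-1 (-0.29) were lower, 2 of 6, or 3 adjusted over the list alone, and 0 were higher (list adjusted p = 0.129). The value of mmcm-1 turned to 0.012 with the hybridisation controls set equal, and its other probe set gave another call, as did others of pcca-1 and pccb-1. The differences of pcca-1 (-0.30), pccb-1 (-0.19), mmaa-1 (-0.09) and mmab-1 (-0.15) did not pass.

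Many germ-cell genes differed between the Comamonas diets. Of 36 sperm genes 31 were higher on the full diet and 1 lower, also when adjusted over the list alone, with spe-11 (4.26) and the sperm phosphatase genes gsp-3 (4.34) and gsp-4 (4.11) higher and swm-1 (-0.52), named after its values were seen, lower. The sperm median was 3.07 (camera adjusted p = 3.30e-24; adjusted p = 0.15 with an estimated correlation). Of 22 oocyte genes 20 were higher and 2 lower, also when adjusted over the list alone, with cpg-1 (1.99) and puf-5 (1.94) higher and perm-2 (-0.96) and perm-4 (-0.74), named after their values were seen, lower. The oocyte median was 1.24 (camera adjusted p = 7.80e-11; adjusted p = 0.43 with an estimated correlation). Of 30 germline genes 17 were higher, 19 when adjusted over the list alone, and 0 lower, with cyb-1 at 1.46. The germline median was 0.41 (camera adjusted p = 2.48e-07; adjusted p = 0.43 with an estimated correlation), or 0.72 with the hybridisation controls set equal, with 26 higher. All 5 vitellogenins were lower on the full diet, also when adjusted over the list alone, from vit-1 (-0.88) to vit-5 (-0.48), with a median of -0.57 (camera adjusted p = 0.00267; adjusted p = 0.40 with an estimated correlation). Only 2 of them were lower with the hybridisation controls set equal, where the median was -0.27. The 10 genes with the largest positive difference were sss-1 (5.37), C04F12.7 (5.35), K06A5.2 (5.28), C27D6.3 (5.24), R09E10.6 (5.11), T23G11.1 (5.04), F27C1.1 (5.02), nspe-1 (5.01), htas-1 (5.0) and gipc-2 (4.99).

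**Figure D3:**
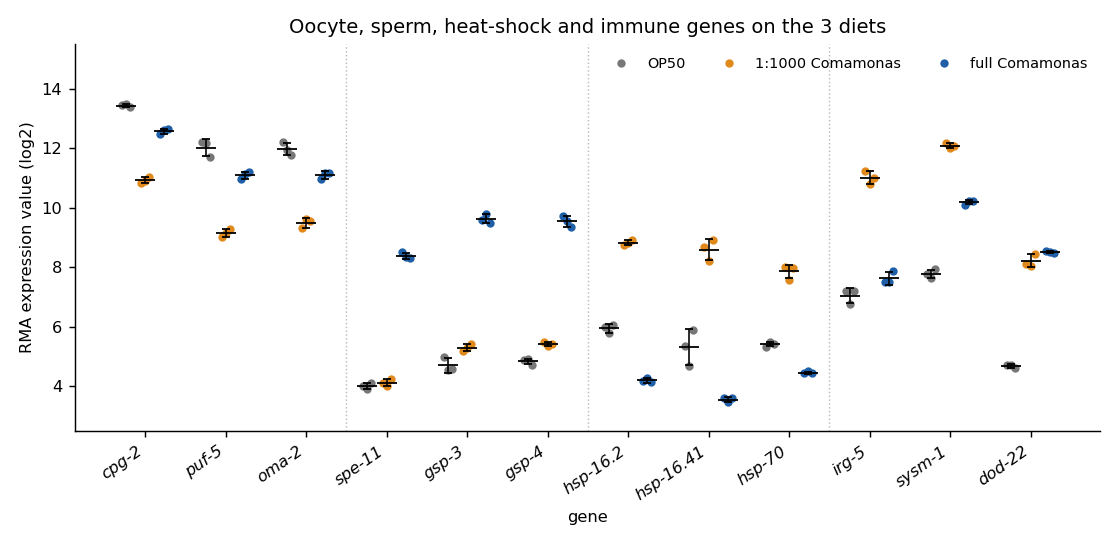
Log2 values (y axis) of 3 oocyte genes, 3 sperm genes, 3 heat-shock genes and 3 immune genes (x axis) on OP50, the 1:1000 diet and the full diet; points are arrays (n = 3 per diet), lines are means and bars are SD. The sperm gene spe-11 stands at 4.01 on OP50, 4.12 on the 1:1000 diet and 8.38 on the full diet, whereas hsp-16.2 is highest on the 1:1000 diet at 8.83.

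Some stress, defence and gut genes were lower on the full than on the 1:1000 diet. The genes hsp-16.41 (-5.04) and hsp-16.2 (-4.63) had the largest negative differences, and hsp-70 (-3.39) followed the same direction, while 7 of 16 heat-shock genes were lower and 3 higher, or 7 and 4 adjusted over the list alone (list adjusted p = 0.0784, its median of -0.08 turning positive, 0.23, with the hybridisation controls set equal). The 3 higher genes were sip-1 (1.21), hsf-1 (0.42) and hsp-1 (0.27), named after their values were seen. Of 58 innate immune genes 28 were lower, 31 when adjusted over the list alone, and 6 higher, with irg-5 (-3.38), irg-4 (-2.58) and irg-2 (-2.61) lower. The immune median was -0.32 (camera adjusted p = 3.76e-05; adjusted p = 0.48 with an estimated correlation). It was -0.02 with the hybridisation controls set equal, with 23 lower and 12 higher. Of 27 protease and lysosome genes 14 were lower and 4 higher, 18 and 5 when adjusted over the list alone, with cpz-1 (-1.65) and asp-4 (-1.44) lower. The protease median was -0.43 (camera adjusted p = 0.00568; adjusted p = 0.57 with an estimated correlation), or -0.12 with the hybridisation controls set equal, with 6 lower and 6 higher. The 4 that were higher, named after their values were seen, were cpr-1 (1.61), cpr-5 (0.96), asp-8 (0.70) and asp-12 (1.26). The remaining negative differences among the 10 largest were those of dpy-14 (-4.24), T02E9.5 (-4.23), drd-50 (-4.22), F15B9.8 (-4.09), clec-266 (-3.99), clec-196 (-3.93) and F07H5.13 (-3.82), with acdh-1.

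Of 14 methionine and folate genes 7 were higher on the full diet and 2 lower, also when adjusted over the list alone, led by sams-5 (2.18) and sams-1 (1.19) against atic-1 (-1.36) and dao-3 (-1.27). The methionine median was 0.22 (camera adjusted p = 0.0442; adjusted p = 0.50 with an estimated correlation), or 0.53 with the hybridisation controls set equal. This list did not pass in 4 of 15 alternatives (adjusted p up to 0.226), and metr-1 was higher by 0.58 while mtrr-1 differed by 0.18 (adjusted p = 0.205). Of 9 adult cuticle collagens 4 were higher, or 5 adjusted over the list alone, and 0 lower, led by col-139 at 3.13. The adult collagen median was 0.27 (camera adjusted p = 0.00568; adjusted p = 0.43 with an estimated correlation). It was 0.57 with the hybridisation controls set equal, with 7 higher. The medians of 4 further lists were negative but turned positive with the hybridisation controls set equal. Higher and lower counts were then 4 and 2 in muscle, 3 and 4 in intestine, 15 and 18 in detoxification and 1 and 6 in oxidative stress and metals. The muscle list did not pass in 2 of 15 alternatives (adjusted p up to 0.0634). In muscle 11 of 25 were lower and 1, tni-1 (0.44), named after its values were seen, higher (1 higher and 13 lower adjusted over the list alone; median -0.27, then 0.03; camera adjusted p = 0.0191; adjusted p = 0.69 with an estimated correlation). In intestine 8 of 17 were lower and 2, cpr-1 (1.61) and ifc-2 (0.34), ifc-2 being named after its values were seen, higher (2 higher and 11 lower adjusted over the list alone; median -0.26, then 0.04; camera adjusted p = 0.0204; adjusted p = 0.57 with an estimated correlation). In detoxification 23 of 61 were lower and 7 higher, also when adjusted over the list alone, with cyp-35A5 at -2.39 and ugt-25 at 2.00 (median -0.17, then 0.13; camera adjusted p = 0.0177; adjusted p = 0.57 with an estimated correlation). In oxidative stress and metals 10 of 21 were lower, among them the superoxide dismutase gene sod-3 (-1.12), and 1, msrp-2 (3.81), was higher, also when adjusted over the list alone (median -0.22, then 0.08; camera adjusted p = 0.0149; adjusted p = 0.48 with an estimated correlation).

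The rest of the lists did not pass in this comparison. Higher and lower counts on the full diet were 1 and 2 of 4 in transsulfuration, with cth-1 at -1.95, 1 and 3 of 10 in branched-chain breakdown, 3 and 9 of 20 in fatty acid synthesis, with fasn-1 at 1.3, and 5 and 11 of 25 in fatty acid oxidation (5 and 13 adjusted over the list alone), with acdh-8 at 3.91. They were 1 and 5 of 26 in the TCA list, with pck-1 at -2.05, 4 and 8 of 22 in the embryonic list (4 and 9 adjusted over the list alone), 8 and 12 of 38 among other collagens and 1 and 5 of 20 in the intracellular pathogen list. They were 3 and 5 of 24 in the unfolded protein response list, 0 and 2 of 75 ribosomal genes (0 and 0 adjusted over the list alone), 2 and 6 of 41 in oxidative phosphorylation (2 and 3 adjusted over the list alone) and 3 and 11 of 32 dietary regulators (3 and 12 adjusted over the list alone), of which nhr-68 (-1.01) was lower and nhr-10 differed by -0.28. They were 5 and 9 of 31 in the DAF-16 list (6 and 10 adjusted over the list alone), with dod-3 at -3.61, 5 and 2 of 21 pharynx markers, 11 and 2 of 40 neuron markers and 3 and 4 of 19 hypodermis, gland or vulva markers (3 and 5 adjusted over the list alone), with wrt-10 at -3.55. Median, mean and test differed in sign for fatty acid oxidation (median -0.36, mean 0.05), pharynx (-0.11, 0.09) and the hypodermis list (0.01, -0.17), of which the pharynx and hypodermis medians also changed sign with the scaling. Where a count was 5 or fewer, its members, named after their values were seen, were cbs-1 (transsulfuration, higher), cth-1 and cth-2 (lower), acdh-4 (branched-chain, higher), bcat-1, bckd-1B and acdh-9 (lower), fasn-1, fat-7 and elo-7 (fatty acid synthesis, higher) and cpt-1, acdh-8, ech-1.1, ech-9 and lipl-1 (fatty acid oxidation, higher). In the TCA list they were idh-1 (higher) and idhg-2, sucl-1, icl-1, pck-1 and fbp-1 (lower), in the embryonic list elt-3, lin-26, die-1 and tbx-9 (higher), in the intracellular pathogen list skr-5 (higher) and pals-28, skr-3, skr-4, cul-6 and fbxa-182 (lower). They were hsp-4, hsp-6 and hsp-60 (unfolded protein response, higher), xbp-1, pek-1, atf-4, pdi-6 and dnj-7 (lower), rpl-23A.1 and rpl-41.1 (ribosomal, lower), ucr-2.3 and cox-15 (oxidative phosphorylation, higher), nhr-23, nhr-66 and skn-1 (dietary regulators, higher) and ins-6, ins-7, ins-33, ins-37 and age-1 (DAF-16, higher). They were also tnc-2, tni-4, mlc-4, abu-8 and abu-11 (pharynx, higher), pha-4 and phat-2 (lower), unc-64 and unc-119 (neuron, lower), and elt-3, grd-3 and vab-10 (hypodermis, higher) and dpy-7, nhr-25, wrt-2 and wrt-10 (lower). Most of these splits turned round with the hybridisation controls set equal, where the median of each list in this paragraph but fatty acid oxidation (-0.06) was positive. The higher and lower counts were then 2 and 1 in transsulfuration, 5 and 0 in branched-chain breakdown, 3 and 2 in fatty acid synthesis, 9 and 6 in fatty acid oxidation, 11 and 3 in the TCA list, 4 and 4 in the embryonic list and 16 and 6 among other collagens. They were 2 and 1 in the intracellular pathogen list, 6 and 1 in the unfolded protein response list, 4 and 0 of the ribosomal genes, 8 and 0 in oxidative phosphorylation, 12 and 4 of the dietary regulators, 12 and 7 in the DAF-16 list, 8 and 0 of pharynx, 17 and 1 of neuron and 6 and 2 of hypodermis markers. The genes cth-2, bckd-1B and rpl-41.1 turned positive there and lost their calls. In total 4051 probe sets were higher and 4013 lower by limma with Benjamini-Hochberg adjustment, 35.8%, and 1040 and 696 by at least 2-fold. The split was 3390 higher and 6382 lower with arrays median-centred, where the median of all probe sets is -0.13, and 7791 and 1441 with the hybridisation controls set equal, where it is 0.25.

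Many of the same transcripts were called on both Comamonas diets against OP50. The genes acdh-1, hphd-1, clec-47, nhr-114, pud-4 and dod-22 were called in the same direction on each, and 6797 probe sets in all were, 2492 higher and 4305 lower, where independent lists of these sizes would share 2154. Another 359 were called in opposite directions, and genes of this kind include hsp-16.2, hsp-70 and pck-1. Both comparisons use the same OP50 arrays, which are too few to split, and this adds to the calls shared by an amount that is not known. To see how far the log2 differences go together from that source, groups without any change, OP50 included, were simulated in 20 runs. The noise was drawn independently for each probe set and array. Deviations that many probe sets of a real OP50 array share are thus absent, and the simulations may understate this source. The covariance of the log2 differences was 0.299 against 0.00737 in the simulations, and their correlation across probe sets, which are not independent, was 0.584 against 0.501. Of the 3972 probe sets higher on the full diet, 2492 were also higher on the 1:1000 diet, and among these the full diet was further from OP50 for 628, the 1:1000 diet for 835 and neither for 1029. Of the 5810 lower on the full diet, 4305 were also lower on the 1:1000 diet, where the full diet was further for 146, the 1:1000 diet for 1815 and neither for 2344.

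**Figure D4:**
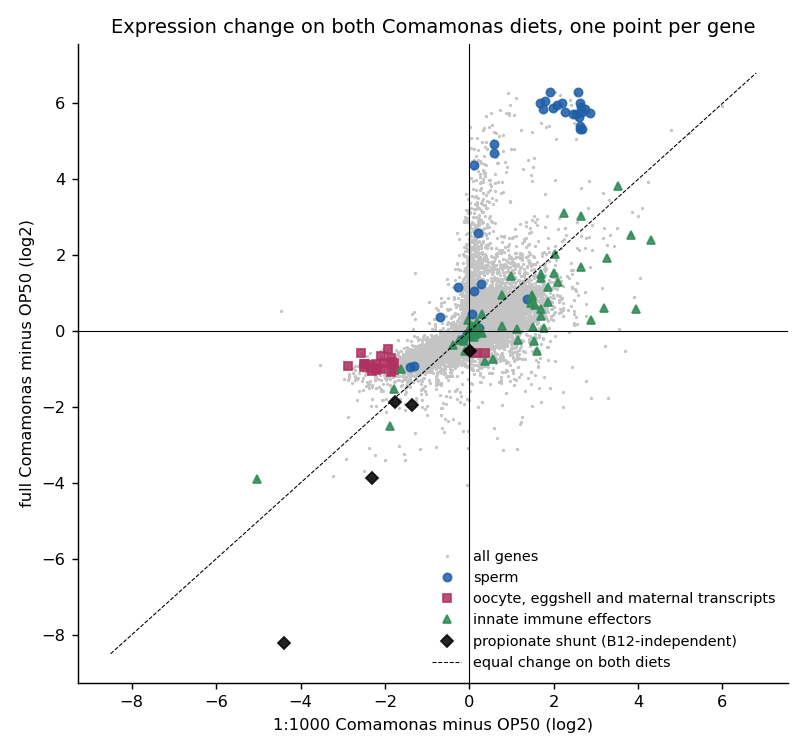
Log2 difference from OP50 on the 1:1000 diet (x axis) and on the full Comamonas diet (y axis), with 1 point per gene, the sperm, oocyte, innate immune and propionate shunt lists coloured, and a dashed line where both differences are equal. Most sperm genes lie above the line (medians 1.77 and 5.37) and so do most oocyte genes (-2.15 and -0.87), while acdh-1 lies below it (-4.40 and -8.21).

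Camera passed 12, 17 and 13 of the 31 lists in the 3 comparisons. With an estimated correlation 0 passed in each (lowest adjusted p 0.154, 0.316 and 0.147). This form has only 6 residual degrees of freedom and little power. The hypodermis list lost its 1:1000 call at a correlation of -0.006, below the preset 0.01, so its correlation is not the cause. Fry asks if a list's genes move one way, not against other genes, and passed 26, 28 and 25.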

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

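All tests weighed here were chosen only after the result was seen, except those of males and of plain probe sets in the sperm list. Of 258 named genes, 33 were called in opposite directions on the Comamonas diets against OP50 and also differed between these diets by limma. Of these, 30 were below OP50 on the full and above it on the 1:1000 diet. The naming rule favours such genes: of all 17118, 251 were called that way and 31 the reverse.

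The values that follow are the full minus the 1:1000 diet on the log2 scale. Heat-shock genes were hsp-16.41 (-5.04), hsp-16.2 (-4.63) and hsp-70 (-3.39). Others were dpy-14 (-4.24), wrt-10 (-3.55), T02E9.5 (-4.23), drd-50 (-4.22), F15B9.8 (-4.09), F07H5.13 (-3.82) and the lectin gene clec-196 (-3.93). Detoxification, stress and pathogen response genes were cyp-35A5 (-2.39), cyp-25A1 (-2.33), sod-3 (-1.12), mtl-2 (-0.88), pek-1 (-0.92), xbp-1 (-0.47) and skr-4 (-1.25). Gut and lysosome genes were cpz-1 (-1.65), ges-1 (-1.47), asp-4 (-1.44) and cpr-6 (-1.21). Metabolic genes were pck-1 (-2.05), cth-1 (-1.95), atic-1 (-1.36) and dao-3 (-1.27), with the regulator mxl-3 (-2.15). Yolk and eggshell genes were vit-1 (-0.88), vit-4 (-0.57), vit-6 (-0.57) and perm-2 (-0.96). The 3 genes above OP50 on the full diet and below it on the 1:1000 diet were nspe-1 (5.01), fasn-1 (1.3) and tni-4 (0.79). The 1:1000 differences from OP50 of mtl-2 (0.27), sod-3 (0.27), xbp-1 (0.25), vit-4 (0.22), vit-6 (0.25) and tni-4 (-0.22) are no larger in size than the offset of the hybridisation controls.

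Control probe sets, which no comparison of the report tests, differed between diets. The mean of the hybridisation controls was higher by 0.28 and that of the poly-A controls by 0.26 on the 1:1000 diet than on OP50. Between the Comamonas diets, the former averaged 10.14 on the 1:1000 and 9.84 on the full diet, and the latter 5.16 and 4.76. The log2 ratios of 3' to 5' probe sets on OP50, the 1:1000 and the full diet were -0.12 ± 0.07, -0.15 ± 0.12 and 0.09 ± 0.04 for Gapdh, 3.6 ± 0.12, 3.84 ± 0.04 and 3.83 ± 0.05 for ubiquitin, 1.08 ± 0.19, 1.25 ± 0.04 and 1.48 ± 0.15 for catalase, and 0.70 ± 0.16, 0.56 ± 0.12 and 0.51 ± 0.02 for actin (SD, n = 3). Whether RNA quality differed was not tested.

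Sperm transcripts were higher on the full diet than on OP50. Males among the animals would bring male-specific genes outside the germline, whose median difference was -0.074 with 0 of 9 called, but only 1 of the 9 is above the array median, so a small share of males cannot be told apart. Cross-hybridisation between near-identical sperm genes predicted a small median over the plain _at members, and that median was 0.66 against 5.76 over the other 26, so it may enlarge the list's median. Of the 195 genes at least 8-fold higher, 60% have plain _at probe sets (117 genes, against 74.8% of all genes). Which of these are sperm genes was not tested, and the bound for this share was chosen after the values were seen. This share therefore does not decide. Animals at an earlier reproductive stage, a biological explanation, would also carry fewer embryos, and the median of the embryonic zygotic list was -0.37, lower than in all but 0.01% of 10000 random lists. Camera did not pass this list (adjusted p = 0.0622; adjusted p = 0.36 with an estimated correlation). On the 1:1000 diet its median of only -0.05 was also lower than in all but 3.25% of random lists. Stage, males, the diet itself and, for the list's median, cross-hybridisation remain open.

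Oocyte transcripts were lower on the 1:1000 diet than on OP50. Under quantile normalization the oocyte median was -2.04. RMA includes a quantile step of its own, so if the arrays were normalized together, repeating that step tests little. Median-centring (-2.25) and equal hybridisation controls (-2.43) shift each array by a small constant, so they could not move the oocyte median far and test little. The fall thus held under each of these scalings, but they do not decide whether scaling plays a part. A lower share of germline RNA alone would raise every somatic tissue alike, and the medians of muscle (1.23), intestine (0.80), neuron (0.61) and hypodermis (0.55) markers spanned 0.68 (permutation p = 0.182 over 43 genes and 10000 permutations), which does not decide. Pharynx markers are left out of this span, as only 2 were high enough on OP50. The median of these 2 was -0.11, and that of all 21 pharynx markers was 0.06. This form of the test replaced earlier ones after their values were seen: the first rested on the 2 pharynx genes, and the next, which did pass its threshold, compared the highest with the lowest list without allowing for their choice. A smaller germline and a change within oocytes cannot be told apart by this test, and the diet stays untested as a direct cause.

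The inducible heat-shock genes hsp-16.2, hsp-16.41 and hsp-70 were higher on the 1:1000 diet than on OP50. A single stressed culture or array is argued against, since the lowest 1:1000 array lay above the highest other array by 2.69, 2.31 and 2.11 on the log2 scale. Over the whole list of 16 heat-shock genes the median was 0.0051 (SD 1.59), with 7 higher and 7 lower, so its members did not rise together. The bound set for this test took in the SD over genes, the 3 inducible genes included. It could therefore hardly decide whether the list rose in general. This form of the test replaced one that left out these 3 genes, after its value was seen. A stress shared by all 3 cultures of that diet, such as handling on a day of its own, and a response to the diet remain open, because the sources used here give no harvest batches.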

How the results depend on the processing

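Hybridisation controls set equal, germline-like probe sets left out and the settings for the gene families are tests chosen only after the results were seen. Of 426 results for named genes, 405 called, 0 reversed under any alternative but the hybridisation controls, and 14 lost their call when some array was left out. Counts are printed here where they left the range within 1.5 times the main value, and for these the cause was not tested except that plain _at probe sets and a fold minimum test or keep fewer probe sets by construction. Quantile normalization, the low-value filter, the trended and robust prior, array weights and the fit of only 6 arrays kept each count they were run on within 1.5 times.

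With arrays median-centred, 12419 probe sets were lower on the full diet than on OP50 and 6382 lower than on the 1:1000 diet. With only plain _at probe sets, 2505 were higher and 3293 lower on the full diet, 3061 higher and 2792 lower on the 1:1000 diet, 2292 higher on the full than on the 1:1000 diet, 7590 differed by the F-test and 3800 changed the same way on both diets. At an adjusted p under 0.01, 2555 were lower on the full than on the 1:1000 diet. With at least 2-fold, the higher and lower counts were 1474 and 552 (full against OP50), 1441 and 1710 (1:1000 against OP50) and 1040 and 696 (full against 1:1000), with 4303 by the F-test and 832 changed the same way. With the hybridisation controls equal, 2613 were higher and 8221 lower on the 1:1000 diet, and 7791 higher and 1441 lower on the full than on the 1:1000 diet. Without germline-like probe sets, which were picked on the same arrays so that counts drop by construction, 2547 were higher and 3369 lower on the full diet, 2626 lower on the 1:1000 diet, 678 higher on the full than on the 1:1000 diet, and 3852 changed the same way. Of 93 list results camera passed 42, and 0 with an estimated correlation, but 79 by fry. Of 165 families camera passed 45, 42 and 17 in the 3 comparisons, and 0 with an estimated correlation. With the hybridisation controls equal, values called with the deposited scaling turned sign and lost their call, the cause not being tested: vit-6 (-0.034) and vit-4 (-0.067) for the 1:1000 diet against OP50, and mmcm-1 (0.012), cth-2 (0.060), bckd-1B (0.087), rpl-41.1 (0.017) and nduf-6 (0.022) for the full against the 1:1000 diet.

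Leaving out each array in turn gave 3583 to 4047 higher and 4987 to 5908 lower on the full diet, 4197 to 4685 and 4730 to 5051 on the 1:1000 diet, 3362 to 4100 and 3174 to 4104 between these diets, 11380 to 12059 by the F-test, 5872 to 6909 changed the same way and 39 to 45 lists. The named gene results that lost their call without some array were mmcm-1 for the full diet against OP50 (-0.29 without full-diet replicate 1), tni-4, vit-4, vit-6, tnt-4 and fbxa-182 for the 1:1000 diet against OP50, and mmcm-1, cth-2, bckd-1B, nduf-6, ucr-2.2, bcat-1, skr-5 and rpl-41.1 for the full against the 1:1000 diet. Lists that lost theirs without some array were, with the highest adjusted p over 15 alternatives, fatty acid synthesis (0.329) and intestine (0.125) on the full diet, transsulfuration (0.0624), ribosomal (0.168) and hypodermis (0.0621) on the 1:1000 diet, and muscle (0.0634) and methionine (0.226) between these diets. Only with the hybridisation controls equal did ribosomal genes on the full diet (0.223) and fatty acid synthesis on the 1:1000 diet (0.105) lose it. Arrays with the same replicate number did not deviate together (r above 0.1 in 2 of 9 pairs), and with the number as a block the counts were 3991 and 5701, 4751 and 5042, and 3996 and 3973, with 12188 by the F-test, 6764 the same way, 41 lists and 103 families.

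Signal over background is not known here, so differences of genes near the lower end of the scale are least certain.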

Other observations

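The families described here were picked after their values were seen, while the tests of the splits and of X-linked genes were set before. Gene families sharing a symbol showed further shifts on both Comamonas diets against OP50. On the full diet 82 of 128 collagen genes (col) rose and 0 fell, with a median log2 difference of 0.45 (camera adjusted p = 1.52e-15; adjusted p = 0.38 with an estimated correlation). Of 40 transthyretin-like genes (ttr) 29 rose and 3 fell (median 0.62), of 58 neuropeptide-like genes (nlp) 33 rose and 3 fell (0.38), and of 25 FMRFamide-like genes (flp) 16 rose and 1 fell (0.45). Of 18 vacuolar proton pump genes (vha) 14 rose and 0 fell (0.49). Nuclear pore genes (npp) fell, 19 of 26 with 0 higher (-0.50), as did 23 of 34 vacuolar sorting genes (vps, -0.53) and 49 of 95 F-box genes (fbxb, -0.29). With an estimated correlation the adjusted p of these families lay between 0.34 and 0.45.

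On the 1:1000 diet the nuclear pore genes fell further, with 24 of 26 lower and 0 higher and a median of -1.02 (camera adjusted p = 5.90e-11; adjusted p = 0.40 with an estimated correlation), and between the Comamonas diets 21 of them were higher on the full diet and 0 lower (0.48). Of 13 proteasome regulatory genes (rpn) 12 fell and 0 rose (-0.81), and of 16 cell division cycle genes (cdc) 13 fell and 1 rose (-0.91). Of 32 carboxylesterase genes (cest) 21 rose and 0 fell (0.76), of 64 glucuronosyltransferase genes (ugt) 37 rose and 3 fell, and 73 collagen genes rose with 0 lower. The collagen median of 0.30 is close to the offset of the hybridisation controls, 0.28. With an estimated correlation, a form with little power, the adjusted p of these families lay between 0.40 and 0.50, and 0 of 165 passed.

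X-linked genes were asked about on the premise, not tested for oocyte genes, that genes that follow germ-cell content are seldom X-linked. Among genes at least 2-fold higher on the full diet than on OP50, 10.9% were X-linked (134 of 1225) against 14% of other genes (Fisher's exact p = 0.00225). The share lay between the bounds set before the test, at most 0.7 times or at least 0.9 times that of other genes, so the test does not decide. Of genes at least 2-fold lower on the 1:1000 diet, 6.73% were X-linked (81 of 1204), against 14.3% of others (Fisher's exact p = 1.82e-15). The lower bound was met, germ-cell genes among them remain a hypothesis, and the p-values treat co-varying genes as independent.

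Other splits of the arrays were counted beside the numbers of probe sets called. For the comparisons of 3 against 3 arrays only 10 splits exist, which are too few for a share under 0.05: the real split called 9782, 9874 and 8064 probe sets and the highest other called 0 in each, so 1 of 10 splits reached the real count. For the F-test over 3 diets, 1 of 100 splits, the real one, called as many as 12324 probe sets, and the highest other called 5273. The real split is always among those counted, so 1 of 100 is the lowest share this count could give. A batch that goes with diet would give the same result and was not tested.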
